A study of Mus musculus with 12 samples.

How the data were processed

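Total RNA of AML12 cells, a mouse hepatocyte line, was sequenced in 12 libraries, 3 in each of 4 groups. The groups were control cells, cells treated with FK228, cells overexpressing the YF mutants of class I histone deacetylases (HDACs), and cells given both. Per the labels, RNA was extracted with TRIzol and read as paired ends on a BGISEQ platform. The sample descriptions of the control and FK228 libraries carry a GFP code that the labels do not explain. Doses, treatment times, the HDACs that were mutated and the sequences of the constructs are not given in the sources used here. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

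The deposited values are expected counts per gene, per the file headers. The authors made these estimated counts before deposit without scaling them to library size, as the column totals show, and 16.6% of the values are not whole numbers. The submitters' processing notes name HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12, DESeq2 1.4.5 and the build GRCm38.p6, without a role or an order. The annotation behind the counts and any filter on genes are not given in the sources used here, nor is whether strand was used. Deposited FPKM, TPM, normalized counts and group averages were not used here. The table holds 19037 genes, each with a count in at least 1 library. Of these, 18980 matched the RefSeq table of GRCm38.p6 by gene ID, and positions are given in that build. Mitochondrially encoded mRNAs were not analysed here.

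The estimated counts were rounded to whole numbers. Libraries held 23664446 to 26122998 counts. Genes with too few counts were removed with edgeR's filterByExpr, which left 13346 genes for testing. Library sizes were scaled by TMM, and a quasi-likelihood model with robust dispersions was fitted to the 12 libraries with 1 term per group (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Contrasts compared FK228, YF and the combination with control, the combination with each single treatment, and the FK228 effect with YF against that without it (the interaction). Calls are at a Benjamini-Hochberg adjusted p of 0.05. A direct contrast of FK228 with YF was added after seeing the data. Levels are CPM (counts scaled to library size) with TMM factors, given as the mean ± SD of 3 libraries, and log2 fold changes carry the SE of the fit. Median control levels of lists are CPM without TMM factors. For genes with few counts in a group, the ratio of summed counts is given with a 95% exact interval, which covers counting error only because the reads carry no molecular identifiers.

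The tests, the alternatives, 42 gene lists and the rule for named genes were fixed before the data were examined. Of the 1079 list members, 1046 are in the table and 880 were tested, and 41 lists had at least 3 tested genes. The rule named, for each comparison with control and for the interaction, the 10 highest and 10 lowest log2 fold changes among called genes with a mean CPM of 5 or more, a proper gene symbol and, except for the interaction, groups whose libraries do not overlap. It also named every class I HDAC gene, and up to 4 called members of each list with the largest changes and a mean CPM of 1 or more. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 41 lists of a comparison, and again with a correlation estimated per list. Camera asks whether a list moved relative to other genes. A gene near 0 in control passed the count filter only through a treated group. Lists with low control levels therefore lean towards higher in comparisons with control. Beside it, members were counted over all genes tested and adjusted over the list alone.

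The size of the FK228 effect with YF against that without was measured by total least squares through the origin, over genes called for the mean FK228 effect, with a jackknife over replicate numbers. Chance agreement between comparisons that share the control libraries was measured in 20 simulations of unchanged groups, with the control libraries simulated as well. As 1 alternative, library sizes were scaled by RLE in edgeR, the method of DESeq2 size factors and named so below. The others were no count filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom and a fit to the compared groups alone. The replicate number was also added as a factor, and each of the 12 libraries was left out in turn. The scripts were tested on simulated counts of 13346 genes. For FK228 versus control, 75.8% of 66 genes changed by a log2 fold of 0.5 were called, 86.6% of 67 changed by 1 and 94% of 67 changed by 2, with 11 false calls among 182. A simulated slope of 0.5 was recovered as 0.498 over called genes that had been changed. This leaves out false calls, which the slope in the data may include. Replicate libraries were compared by chi-square over genes with a count of 50 or more. The mean chi-square per gene and pair lay between 3.58 and 21.56, so each pair differed by more than sampling noise and no library counted as a duplicate.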

Results

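RNA was measured in AML12 cells, a mouse hepatocyte line, under 4 conditions with 3 libraries each. The study set the effect of FK228 (romidepsin, an inhibitor of class I HDACs) beside that of overexpressing YF mutants of class I HDACs, alone and together. Total estimated counts ranged from 23664446 to 26122998 per library. The first principal component held 71.1% of the variance and the second 11.8%, and libraries of a group lay together on both. Of 13346 genes tested, 9181 (68.8%) were called in FK228 versus control, 4357 (32.6%) in YF versus control and 10325 (77.4%) in the combination versus control, by edgeR's quasi-likelihood test.

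Hdac1, which encodes a class I deacetylase, stood at 97.7 ± 5.14 CPM in control, 110 ± 3.3 with FK228, 402 ± 18.9 with YF and 798 ± 2.16 with both. In YF versus control Hdac1 rose by a log2 fold change of 2.04 ± 0.06 (adjusted p = 6.12e-16, edgeR), and FK228 raised it by a further 0.99 ± 0.06 in YF cells (adjusted p = 2.01e-12). Hdac8 rose from 17.9 ± 0.567 to 42.1 ± 2.02 CPM with YF, a log2 fold change of 1.23 ± 0.07. Hdac2 was 176 ± 7.6 CPM in control and 189 ± 4.75 with YF, and Hdac3 was 105 ± 2.66 and 113 ± 3.07, and neither passed the test (adjusted p = 0.165 and 0.13). In FK228-treated cells YF raised both, Hdac2 from 149 ± 4.99 to 177 ± 10.4 CPM (0.25 ± 0.06, adjusted p = 0.000963) and Hdac3 from 113 ± 2.34 to 144 ± 3.39 (0.34 ± 0.05, adjusted p = 1e-05), so that 4 of 4 class I HDAC genes were higher there (also adjusted over the list alone; camera adjusted p = 1.49e-12, and 0.00896 with an estimated correlation). FK228 alone lowered Hdac2 by -0.24 ± 0.06. Its effect on Hdac1 alone was 0.17 ± 0.06 (adjusted p = 0.0128), a call that ended without control replicate 3 (log2 fold change then 0.13). The labels do not say which HDACs were introduced, and reads from constructs that differ in sequence from the mouse genes may not have been counted. Reads from constructs that match may have been counted as the mouse genes. A rise of this list with YF may therefore only read out the overexpression. Hdac1 lies on chromosome 4 from 129516104 to 129542646, Hdac2 on 10 from 36974297 to 37001889, Hdac3 on 18 from 37936971 to 37955015 and Hdac8 on X from 102284638 to 102505381 (GRCm38.p6).

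**Figure D1:**
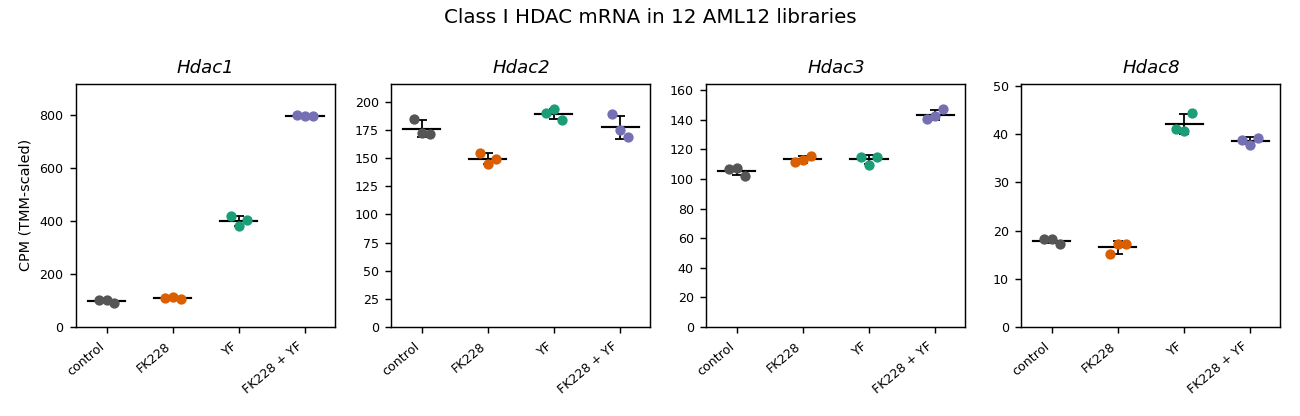
TMM-scaled CPM of the 4 class I HDAC genes in each of the 12 libraries, with the group mean (long bar) and SD (error bar, n = 3). Hdac1 and Hdac8 are higher in every library with YF than in every library without it, and Hdac1 is highest with both treatments.

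FK228 versus control asked what the inhibitor does to gene expression in cells without YF. Genes of cell division fell together: 41 of 41 tested genes of the Mitosis list were lower and none higher, with a median log2 fold change of -2.37. Kif20a, a kinesin of cytokinesis, went from 142 ± 11.4 to 20.2 ± 2.33 CPM (-2.81 ± 0.10), and Cdc20, an activator of the anaphase-promoting complex, from 54.7 ± 3.58 to 7.91 ± 0.729. Of 45 DNA replication and S phase genes, 43 were lower and none higher (median -1.52), among them the helicase subunit Mcm5 (-2.21 ± 0.12) and the checkpoint mediator Clspn (-2.31 ± 0.18). Counts adjusted over the list alone were again 41 and 43. Camera gave adjusted p = 1.73e-72 for mitosis and 3.5e-26 for replication, which became adjusted p = 0.063 and 0.164 with an estimated correlation.

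The genes that FK228 raised most started near 0 in control. Cd36, a fatty acid transporter gene (chromosome 5, 17781690 to 17888959), rose from 0.0516 ± 0.0592 to 14.5 ± 0.921 CPM, a ratio of 280 with a counting interval of 109 to 1030. Hba-a1, an alpha globin gene, rose from 0.0515 ± 0.0446 to 34.3 ± 6.11 CPM (ratio 664, interval 259 to 2440), and its value is uncertain because reads may be split with the near-identical Hba-a2. Gli1, a transcription factor of Hedgehog signalling, rose from 0.18 ± 0.0889 to 13.4 ± 0.568 CPM. The antiviral genes Rsad2 (6.31 ± 0.20) and Oas1a (6.22 ± 0.22, one of several similar Oas1 copies), the interferon-inducible Apol9a (5.85 ± 0.27), Gsdma, Ndrg2, Cntnap2 and Map1a completed the 10 highest. Of the 10 lowest, Cybb, a subunit of the phagocyte NADPH oxidase, fell from 12.4 ± 1.82 to 0.573 ± 0.219 CPM (-4.42 ± 0.23). The cytochrome P450 gene Cyp2c68 (-4.24 ± 0.21), the glutathione enzyme Ggt1 (-4.10 ± 0.19), Spon2, the antitrypsin genes Serpina1d and Serpina1b, the chemokines Cxcl17 and Ccl9, Pde4c and the histone gene H2ac10 made up the rest. Reads of Serpina1b, Serpina1d, Cyp2c68 and H2ac10 may be split with close paralogs.

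Chromatin genes moved in both directions with FK228. Of 16 tested genes of the replication-dependent histone list, 14 were higher and none lower (also adjusted over the list alone), with a median of 3.36, or 3.18 with genes of 3 or fewer control counts at their bound. The median control level of the 28 list members in the table was 0.148 CPM. The linker histone gene H1f2 rose from 5.73 ± 0.318 to 81.8 ± 9.17 CPM, while H2ac10, a more abundant histone gene outside the list, fell from 91.9 ± 13.4 to 7.57 ± 2.7 CPM. Of 38 HDAC corepressor genes, 24 were lower and none higher (23 adjusted over the list alone; 21 lower and 1 higher with DESeq2 size factors), led by the remodeller Chd3, which fell from 470 ± 23.7 to 90 ± 4.18 CPM (-2.38 ± 0.06). Among 19 histone acetyltransferase and bromodomain genes, 16 were lower, including the acetyltransferase genes Crebbp (-1.18 ± 0.15), Kat2b (-1.12 ± 0.09) and Kat2a (-0.88 ± 0.06), and 1 was higher (the same counts adjusted over the list alone). Neuronal genes repressed by REST rose, 12 of 20 tested with 1 lower (also adjusted over the list alone), such as the neuropeptide precursor gene Vgf from 5.63 ± 0.807 to 36.2 ± 2.02 CPM. The median control level of the 40 list members in the table was 0.0453 CPM. Because members silent in control were tested only if a treated group had counts, the histone and REST results lean towards higher. Camera gave adjusted p = 3.17e-08 for histones, 0.00857 for corepressors, 0.00419 for acetyltransferases and 5.84e-05 for the REST list. These became adjusted p = 0.0654, 0.0654, 0.164 and 0.0654 with an estimated correlation.

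Some stress, immune and metabolic lists also moved with FK228, and others did not pass camera. Interferon stimulated genes rose, 21 of 29 with 1 lower (also adjusted over the list alone; median 1.41), and Usp18, a brake on interferon signalling, went from 1.44 ± 1.06 to 21.3 ± 2.24 CPM. NRF2 targets rose, 18 of 23 with 2 lower (18 and 3 adjusted over the list alone; median 0.67), such as the heme oxygenase gene Hmox1 from 89.1 ± 7.52 to 494 ± 45.4 CPM. Of 32 lysosome and autophagy genes, 25 were higher and 4 lower (also adjusted over the list alone; median 0.69), and the protease gene Ctsl went from 247 ± 7.77 to 1050 ± 47.4 CPM. Glycolysis and hypoxia genes were higher in 19 of 27 and lower in 2 (20 and 2 adjusted over the list alone). The 18 textbook HDAC inhibitor responders included 11 higher and 2 lower (also adjusted over the list alone), with Clu at 1260 ± 131 and 4680 ± 79.6 CPM. Of 28 hepatocyte identity genes, 17 were lower and 4 higher (also adjusted over the list alone; median -0.70), among them the gene of the thyroxine carrier Ttr (-3.34 ± 0.33). Acss2, which makes acetyl-CoA from acetate, rose from 7.19 ± 0.561 to 59.4 ± 2.63 CPM, while the fatty acid synthase gene Fasn fell by 1.08 on the log2 scale. Camera's adjusted p values for these 6 lists, in that order, were 6.45e-11, 1.76e-10, 5.23e-11, 0.000181, 1.1e-05 and 0.0044. With an estimated correlation they were adjusted p = 0.117, 0.063, 0.0863, 0.514, 0.0863 and 0.426. Lists that did not pass included the integrated stress response (8 higher and 12 lower of 30, adjusted p = 0.734), the unfolded protein response (9 and 7 of 23, 0.6), heat shock (5 and 7 of 18, 0.97), NF-kB (11 and 12 of 30, 0.734), cholesterol synthesis (5 and 13 of 25, 0.301) and fatty acid synthesis (11 and 7 of 22, 0.14), with the same counts adjusted over the list alone.

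Lists of other cell types moved in both directions. Cholangiocyte and progenitor markers were lower with FK228 in 5 of 9 and higher in 1 (camera adjusted p = 0.14), and with both treatments 7 of 9 were lower and none higher against control (1 higher with DESeq2 size factors; camera adjusted p = 0.00649) and against FK228 alone (camera adjusted p = 0.00122), each also adjusted over the list alone. The last 2 became adjusted p = 0.208 and 0.259 with an estimated correlation. Macrophage and leukocyte markers were higher with FK228 in 4 of 8 and lower in 2 (also adjusted over the list alone; camera adjusted p = 0.481). Mesenchymal markers were higher with FK228 in 7 of 14 and lower in 3 (also adjusted over the list alone; camera adjusted p = 0.108). Of 3 tested hepatic stellate cell markers, 2 were higher with FK228 and none lower (camera adjusted p = 0.00857), and 3 were higher with both treatments (camera adjusted p = 0.0188), each also adjusted over the list alone. The stellate calls became adjusted p = 0.279 and 0.298 with an estimated correlation. The median control level of the 10 stellate markers in the table was 0.0451 CPM, so the count filter tilts these calls towards higher. In all 4437 genes were higher and 4744 lower with FK228, of which 1475 and 1032 changed at least 2-fold, and 14 of 41 lists passed camera, none of them with an estimated correlation.

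YF versus control asked what the mutants do without the inhibitor. The gene with the largest rise was H3c13, a replication-dependent histone gene on chromosome 3 (96268654 to 96269155, gene ID 319154), from 0.0389 ± 0.0673 to 29.7 ± 3.68 CPM, a ratio of 767 with a counting interval of 262 to 3720. Fos, an immediate early transcription factor gene (chromosome 12, 85473890 to 85477274) rose from 1.08 ± 0.153 to 47.8 ± 5.15 CPM (5.46 ± 0.13, adjusted p = 1.12e-17, edgeR). Hba-a1 (20.6 ± 5.68 CPM), Cd36 (2.02 ± 0.174 CPM), Gli1 (4.96 ± 0.27), the histone gene H3c11 (4.72 ± 0.34), the complement protease C1s1 (4.47 ± 0.21), Serpina3i (4.42 ± 0.15), Ndrg4 (4.33 ± 0.21) and Serpinb1a (4.12 ± 0.21) made up the rest of the 10 highest. H3c13 and H3c11 belong to a family of near-identical genes, so reads may be split between copies. Decreases were smaller: Fxyd2, a regulator of the sodium pump, fell from 37.7 ± 7.83 to 7.65 ± 2.37 CPM (-2.30 ± 0.22), and Ptgds, Serpina1d, Serpina1b, Ggt1, Pipox, Sema3a, Neurl1b, Nfia and Acnat1 lay between -2.16 and -1.38.

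Some lists of stress and signalling genes lay higher with YF relative to other genes, by small amounts and with many members not called. Integrated stress response genes were higher in 20 of 30 and lower in 1 (21 and 2 adjusted over the list alone; median 0.31), such as the glutathione-degrading enzyme Chac1 (0.78 ± 0.14) and Ddit3 (0.57 ± 0.06), which encodes CHOP. Unfolded protein response genes were higher in 15 of 23 and lower in none (also adjusted over the list alone), with Creld2 at 0.55 ± 0.06. Of 31 p53 targets, 16 were higher and 2 lower (19 and 2 adjusted over the list alone), among them the cell cycle inhibitor Cdkn1a (0.46 ± 0.06) and the ubiquitin ligase Mdm2 (0.60 ± 0.05). Of 23 immediate early genes, 8 were higher and 2 lower (also adjusted over the list alone), with Fosl1 at 1.15 ± 0.12 and Dusp5 at 1.12 ± 0.10. Of 20 REST-repressed neuronal genes, 9 were higher and 1 lower (also adjusted over the list alone), such as the synaptic vesicle gene Syp (1.37 ± 0.14). The count filter tilts this list upward here too. Lysosome genes were higher in 16 of 32 and lower in none (17 adjusted over the list alone), and mesenchymal markers in 7 of 14 with 2 lower (9 and 2 adjusted over the list alone), including the fibronectin gene Fn1 (1.08 ± 0.08). Camera gave these 7 lists adjusted p = 0.000196, 0.00101, 0.000567, 3.77e-05, 0.000414, 0.00101 and 0.00979. With an estimated correlation they were adjusted p = 0.452, 0.115, 0.0815, 0.0815, 0.111, 0.452 and 0.164.

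Fewer lists moved down with YF. Of 40 cytosolic ribosomal protein genes, 13 were lower, none higher and 27 not called (13 lower also adjusted over the list alone, and 22 lower with DESeq2; median -0.19; camera adjusted p = 8.35e-05, and adjusted p = 0.647 with an estimated correlation), such as Rplp0, at 3540 ± 276 and 2870 ± 50.1 CPM. Cholangiocyte and progenitor markers (median -0.10) and epithelial junctions and keratins (median -0.20) also passed camera. Both calls ended without YF replicate 2 (camera adjusted p = 0.0671 and 0.0634) and with an estimated correlation. The keratin gene Krt19 fell from 607 ± 82.6 to 284 ± 24.1 CPM and the hypoxia-responsive Ndrg1 from 293 ± 66.1 to 127 ± 18.8 CPM. In the Mitosis list 1 of 41 genes was called, and none adjusted over the list alone (median -0.02, camera adjusted p = 0.626). That gene was Aspm (0.31 ± 0.10), whose call ended without control replicate 2, control replicate 3, YF replicate 2 or YF replicate 3. Its log2 fold changes were then 0.25, 0.26, 0.25 and 0.33. Interferon stimulated genes were higher in 12 of 29 and lower in 3 (also adjusted over the list alone), with camera adjusted p = 0.0508. In all 2405 genes were higher and 1952 lower with YF, of which 749 and 111 changed at least 2-fold, and 12 of 41 lists passed camera. Of these only the class I HDAC list, with 2 of 4 members higher (also adjusted over the list alone), passed with an estimated correlation (adjusted p = 0.0054). The YF cells were made to overexpress class I HDAC mutants, so this call may only read out the overexpression.

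**Figure D2:**
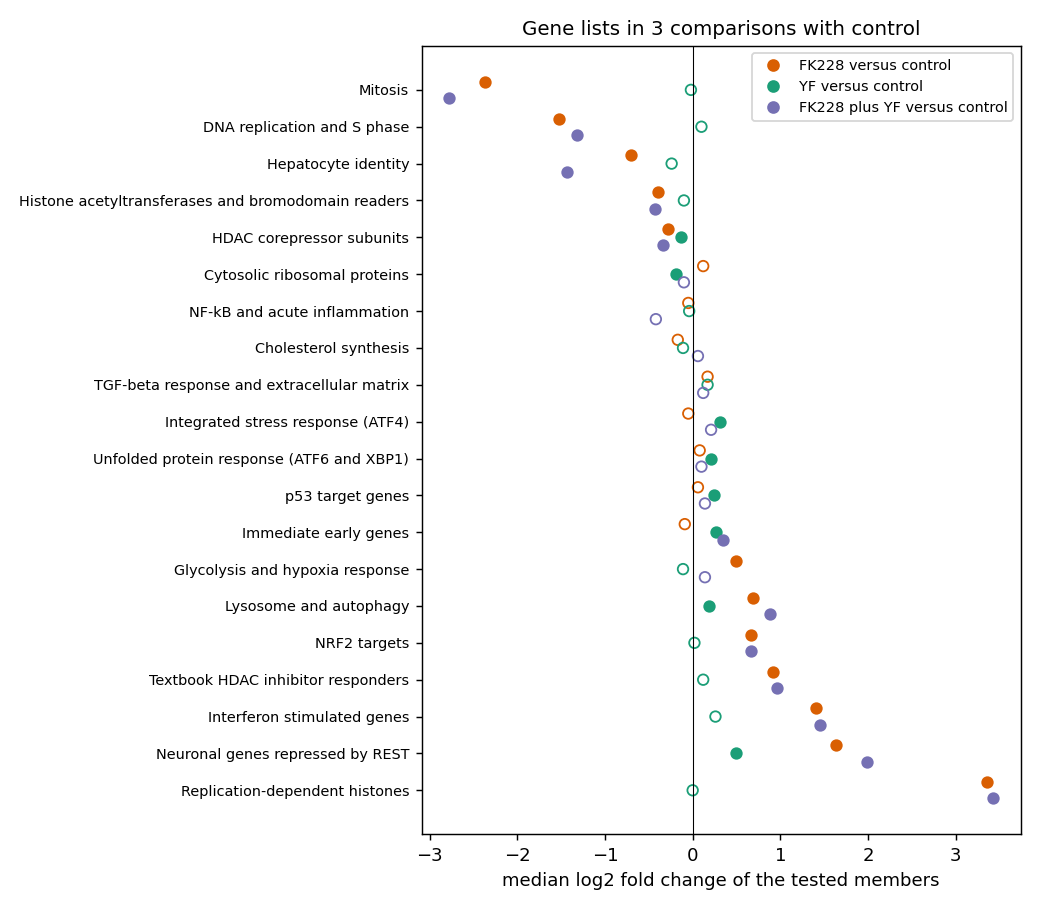
Median log2 fold change of the tested members of 20 gene lists in FK228, YF and FK228 plus YF versus control. Filled circles passed camera at an adjusted p of 0.05 with the preset correlation, and open circles did not. Mitosis genes lie at -2.37 with FK228 and -0.02 with YF.

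Most genes called with YF were called in the same direction with FK228. Of the 2405 genes higher with YF, 1789 (74.4%) were also higher with FK228, where independent lists would share 800, and 180 were lower with FK228. Of the 1952 lower with YF, 1418 (72.6%) were also lower with FK228, where independent lists would share 694, and 167 were higher. Cd36, Gli1, Acss2, Vgf and Hba-a1 rose with each single treatment, and Serpina1d, Ggt1 and Krt19 fell with each. Over tested genes with a mean count above 10, which are not independent replicates, fold changes correlated with r = 0.739. Simulated unchanged groups against shared control libraries, themselves simulated, gave 0.491 in 20 simulations. The simulated genes were picked by counts simulated at control levels. Genes near 0 in control can thus enter the observed values but not the simulated ones, so neither r nor the covariance compares like sets. The covariance was 0.5683 against 0.0153 simulated, a difference of 0.553. The simulated overlaps were 0 and 0.05 genes, and since 3 control libraries are too few to split, part of the excess may come from the shared controls. The FK228 effect averaged over cells without and with YF, and the YF effect averaged likewise, are not correlated by equal sampling noise. Of 6322 genes called for both averages, 5312 went in the same direction and 1010 in opposite ones. An oddity of the control libraries would still enter both.

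Set directly against YF, FK228 gave lower cell cycle genes and higher ribosomal protein genes. All 41 mitosis genes and all 45 replication genes were lower with FK228 than with YF (also adjusted over the list alone), with medians of -2.37 and -1.57. NRF2 targets were higher in 19 of 23 and lower in 2 (also adjusted over the list alone), among them the peroxiredoxin gene Prdx1 (1.59 ± 0.07), and replication-dependent histones were higher in 14 of 16 (also adjusted over the list alone). Of 40 ribosomal protein genes 31 were higher and none lower (also adjusted over the list alone; median 0.31; camera adjusted p = 0.000138), a call lost at adjusted p = 0.602 with an estimated correlation. Of 30 integrated stress response genes 19 were lower and 4 higher (also adjusted over the list alone; camera adjusted p = 0.0114), lost at adjusted p = 0.575 with an estimated correlation. The calls of the mitosis, NRF2 and histone lists passed with an estimated correlation (adjusted p = 0.0321, 0.0321 and 0.0389), and that of replication did not (adjusted p = 0.0861). Fos was lower with FK228 than with YF (-3.72 ± 0.10) and Cd36 higher (2.84 ± 0.14). In all 3714 genes were higher and 4448 lower in FK228 than in YF cells. This contrast was chosen after seeing the data.

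The combination was compared with control and with each single treatment. Mitosis genes were lower in 41 of 41 against control (median -2.78), and 27 of 41 lay below FK228 alone with 1 above (29 and 1 adjusted over the list alone), for instance Ccnb2, a mitotic cyclin gene, at 18.6 ± 0.803 CPM with FK228 and 9.94 ± 1.83 with both. Against FK228 alone, immediate early genes rose in 14 of 23 with 2 lower (also adjusted over the list alone): Fos reached 130 ± 6 CPM, and Dusp1, a MAP kinase phosphatase gene, went from 9.22 ± 1.67 to 31.4 ± 0.866 CPM. REST-repressed neuronal genes rose in 12 of 20 with 1 lower (13 and 1 adjusted over the list alone), and Vgf reached 107 ± 11.6 CPM. The metal-binding metallothionein gene Mt2 stood at 119 ± 19.7 CPM in control, 429 ± 81.8 with FK228, 242 ± 17.6 with YF and 2130 ± 119 with both. Hepatocyte identity genes were lower than with FK228 alone in 13 of 28 and higher in none (11 adjusted over the list alone): Hnf4a, a master regulator of hepatocytes, was at 177 ± 7.51 CPM in control, 50.6 ± 3.32 with FK228 and 28.7 ± 1.24 with both. Camera's adjusted p for these lists against FK228 were 5.78e-05 for mitosis, 6.68e-09 for immediate early genes, 3.2e-06 for the REST list and 0.0116 for hepatocyte identity. With an estimated correlation the immediate early and REST lists kept the call (adjusted p = 0.0226 and 0.0468), while mitosis and hepatocyte identity lost it (adjusted p = 0.776 and 0.605).

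Against control, the combination called 5172 genes higher and 5153 lower, 2018 and 1734 of them at least 2-fold. The highest were Hba-a1 (126 ± 19 CPM), H3c13 (87.8 ± 6.34 CPM), Cd36, Rsad2, Fos, Gli1, H3c11, Oas1a, Apol9a and Rgs16, and the lowest included Serpina1d (-5.57 ± 0.38), Serpina1b (-5.54 ± 0.33) and Cyp2c68 (-5.01 ± 0.22). Against YF, 4635 genes were higher and 4791 lower, and against FK228, 3549 and 3514. Among the 1789 genes higher with each single treatment, 1068 were higher with both than with FK228 alone and 114 lower, and the median log2 fold changes against control were 1.03 with FK228, 0.63 with YF and 1.41 with both. Among the 1418 genes lower with each, 1016 were lower with both than with FK228 alone and 47 higher, with medians of -0.64, -0.33 and -1.05. These medians are over genes picked by the single-treatment calls, which share the control libraries.

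The interaction asked whether the FK228 effect differed between cells with and without YF. In YF cells FK228 also raised the Hdac1 excess over cells without YF, by a log2 fold change of 1.18 ± 0.05. If those reads come from the constructs, cells given both carried more YF mRNA than cells given YF alone. The interaction cannot tell a changed FK228 effect from that, and the comparisons of the combination with single treatments share this limit. A negative interaction means a smaller or more negative log2 fold change with YF, and does not say that the rise in CPM was smaller. On that scale inflammatory genes responded to FK228 less positively, or more negatively, with YF. Of 30 NF-kB and acute inflammation genes, 20 had a negative interaction and none a positive one (22 adjusted over the list alone, median -0.68). The list median of the FK228 effect was -0.05 without YF and -0.38 with it. By DESeq2, 5 members were higher and 19 lower with FK228 in YF cells. Ptgs2, the inducible cyclooxygenase gene, stood at 15.1 ± 1.81 CPM in control, 57.5 ± 2.54 with FK228, 59.9 ± 2.02 with YF and 98.7 ± 10.5 with both (-1.21 ± 0.11). Of 27 TGF-beta and extracellular matrix genes, 17 had a negative interaction and none a positive one (18 and 1 adjusted over the list alone), such as Fn1 at 411 ± 22.8, 1000 ± 79.4, 868 ± 75 and 896 ± 80.2 CPM (-1.24 ± 0.11). Cholesterol synthesis went the other way, with 16 of 25 genes positive and none negative (19 adjusted over the list alone; median 0.41): Dhcr7, the last enzyme of the pathway, stood at 26.8 ± 1.52, 39.9 ± 1.98, 28.6 ± 1.59 and 70.2 ± 4.44 CPM. In the Mitosis list 21 of 41 interactions were negative and 1 positive (24 and 1 adjusted over the list alone). Camera gave adjusted p = 7.96e-12 for NF-kB, 2.31e-06 for TGF-beta, 4.22e-08 for cholesterol synthesis and 4.24e-06 for mitosis. With an estimated correlation the first and second passed (adjusted p = 0.0161 and 0.049), and the others did not (adjusted p = 0.233 and 0.688).

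Single genes with the most negative interactions were Hba-a1 (-6.63 ± 0.80), Cd36 (-4.90 ± 0.42), Gli1 (-4.63 ± 0.31), Ndrg2, Serpinb1a, Cntnap2, Apol9a, C1s1, Map1a and Oas1a. Each lay below 1 CPM in control, and Hba-a1 and Cd36 had 4 control counts each. Those with the most positive were Peg10 (1.82 ± 0.21), an imprinted gene, Mxd1 (1.82 ± 0.20), a partner of MAX, Mt1 (1.62 ± 0.18), Efnb2, Zfp36, Rabl2, Mt2, Mlf1, Xkr8 and Sfxn2. Mxd1 stood at 7.25 ± 1.4 CPM in control, 6.45 ± 0.824 with FK228, 6.11 ± 0.636 with YF and 19.2 ± 1.88 with both. Ass1, a urea cycle enzyme gene, rose from 11.8 ± 1.54 to 38.9 ± 4.83 CPM with FK228 and to 52.7 ± 5.25 with YF, and stood at 34 ± 2.48 with both (-2.35 ± 0.15). In all 1484 interactions were positive and 2047 negative. On the log2 scale the FK228 effect was smaller with YF in 1139 of these 3531 genes and larger in 1758. It was called in opposite directions in 266, and its mean was not called in 368.

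Over the 10337 genes called for the mean FK228 effect, the effect with YF followed that without it with a slope of 0.776 (jackknife SE 0.027, 3 replicate numbers) and r = 0.841 across genes. The slope was 0.615 among the 5116 genes raised by FK228 and 1.129 among the 5221 lowered. The median log2 fold change of the raised genes was 0.53 without YF and 0.55 with it, and 778 of them had a negative interaction and 790 a positive one. Among raised genes with a mean CPM of 50 or more the slope was 1.071, and among lowered ones 1.259. The pooled slope was 0.949 with a filter of 5 CPM in 3 libraries.

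**Figure D3:**
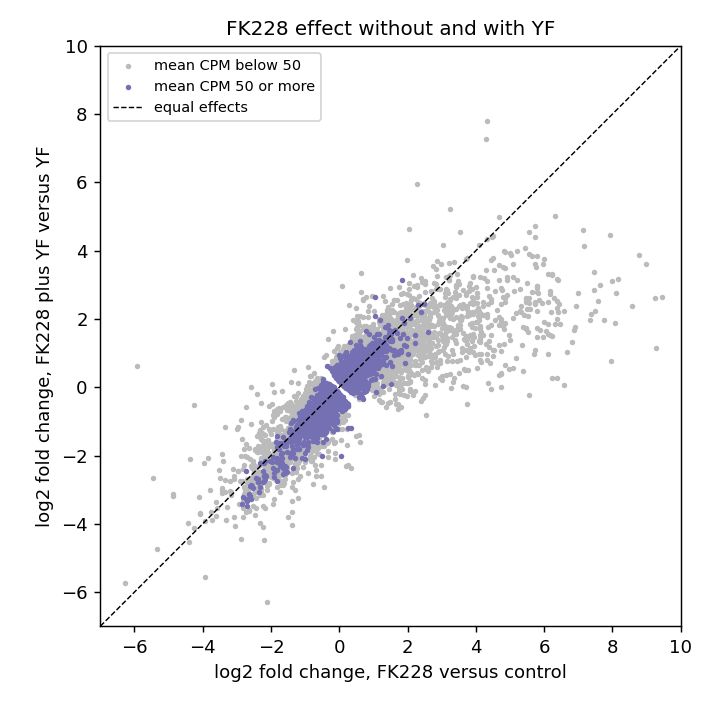
Log2 fold change of FK228 plus YF versus YF (vertical) against that of FK228 versus control (horizontal), 1 point for each of the 10337 genes called for the mean FK228 effect. Grey points have a mean CPM below 50 and purple points 50 or more, and the dashed line marks equal effects.

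**Figure D4:**
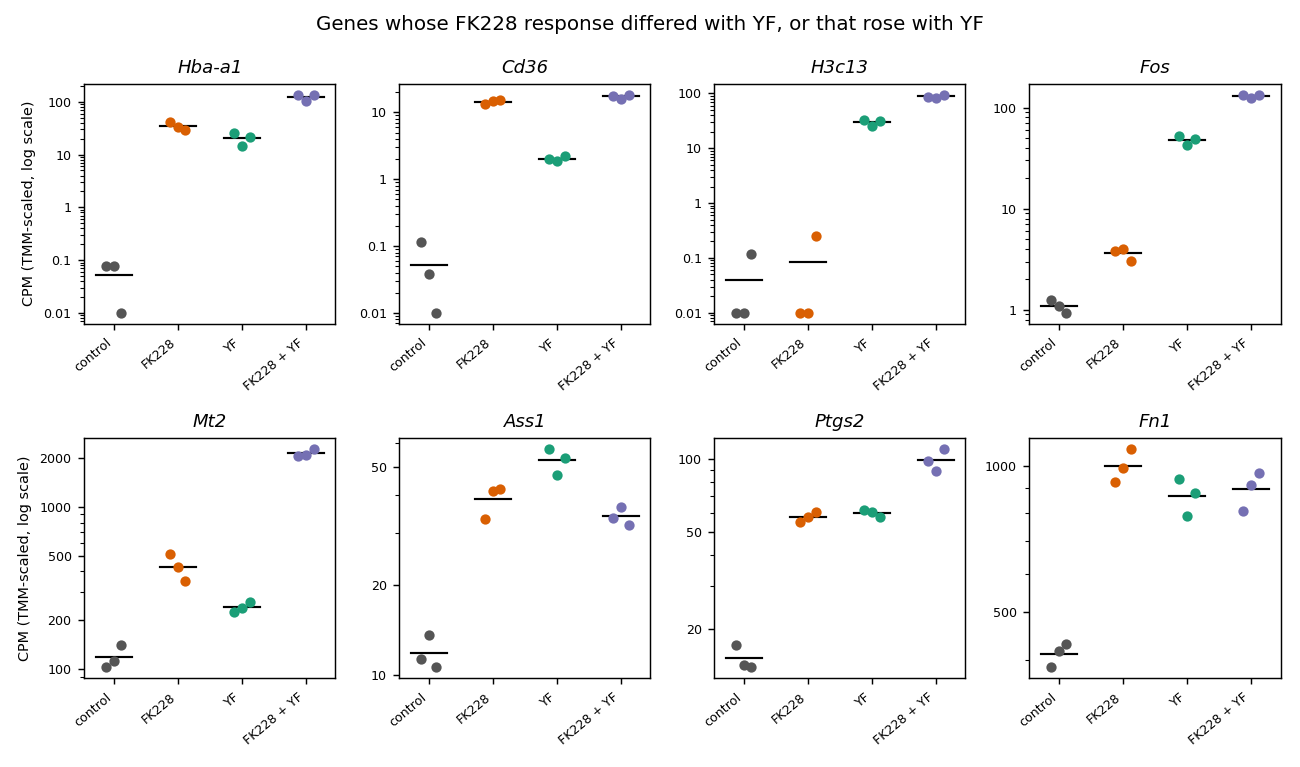
TMM-scaled CPM on a log axis of 8 named genes in each of the 12 libraries, with group means as bars; the 8 were picked from the named genes after their values were seen. Libraries with no count are drawn at the bottom of the axis. The means of Ass1 and Fn1 are lower with both treatments than with FK228 alone, while that of Mt2 is highest with both.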

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

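Of the tests below, those on a few genes taking more of the counts, on an introduced transcript, on other H3 genes, on a general immediate early response and on genes already raised by YF were chosen after the result was seen, as were the comparison of FK228 with YF and the count of splits that keep a group together.

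The FK228 effect differed between cells with and without YF in 3531 genes by the interaction test. The test cannot separate this from a higher level of the YF constructs with FK228, which the Hdac1 reads leave open. Of the gene lists, 9 passed camera for the interaction, with mean log2 interactions of 0.30 for class I HDACs, -0.40 for Mitosis, -0.15 for p53 target genes, -0.31 for hepatocyte identity, -0.50 for xenobiotic and bile acid metabolism, 0.40 for cholesterol synthesis, -0.68 for NF-kB and acute inflammation, 0.14 for immediate early genes and -0.46 for TGF-beta response and extracellular matrix. Camera's adjusted p was 0.0215 for class I HDACs, p53 targets and immediate early genes, 0.0264 for hepatocyte identity and 0.00916 for xenobiotic metabolism. These became adjusted p = 0.305, 0.233, 0.344, 0.668 and 0.656 with an estimated correlation. Members called positive and negative were 2 and 0 of 4, 3 and 13 of 31, 8 and 4 of 23, 0 and 10 of 28, and 0 and 6 of 16 in that order. They were 2 and 0, 3 and 14, 9 and 5, 0 and 11, and 0 and 6 adjusted over the list alone. The class I HDAC call ended without control replicate 1 (0.0512), the p53 call without YF replicate 1 (0.0504) and the immediate early call without FK228 replicate 3 (0.0658). The hepatocyte call ended without control replicate 1 (0.0758), FK228 replicate 2 (0.0559), YF replicate 1 (0.0593) or FK228 plus YF replicate 3 (0.0632).

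Among named genes the same test gave negative log2 interactions of -6.63 for Hba-a1, -4.90 for Cd36, -4.63 for Gli1, -3.47 for Ndrg2, -3.45 for Serpinb1a, -3.32 for Cntnap2, -3.29 for Apol9a, -3.28 for C1s1, -3.14 for Map1a and -2.95 for Oas1a. Positive ones were 1.82 for Peg10 and for Mxd1, 1.62 for Mt1, 1.53 for Efnb2, 1.33 for Zfp36, 1.32 for Rabl2, 1.29 for Mt2, 1.23 for Mlf1, 1.2 for Xkr8 and 1.19 for Sfxn2. Reads of Hba-a1, Oas1a, Mt1 and Mt2 may be split with near-identical copies, which was not tested. The effect of low counts was examined only as a slope over raised genes with a mean CPM of 50 or more (1.071, given with the third pattern). That limit leaves out genes such as Cd36 and Gli1, so the slope does not test their interactions.

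Regrouping the libraries tested whether other splits give as many calls. For the interaction, 100 splits of the 12 libraries were used, and 2 of them, the real one included, gave 3531 calls or more. The highest of the others gave 6736. This share does not decide whether chance can be excluded, because the 93 splits that broke up every group mixed the treatments and gave 0 calls each. Only 7 splits, the real one included, kept a group together, which is too few for a share under 0.05, and 2 of those 7 gave as many calls. The 3 other splits with 1000 calls or more point to a structure of the samples. Each kept the 3 FK228 plus YF libraries together, while the 1 other split that kept the control libraries together gave 7 calls and those for FK228 and for YF gave 0. With 1 such split per group the cause of this difference stays open. For each comparison of 3 libraries with 3, 1 of 10 splits, the real one, gave as many calls, and 10 splits are too few for a share under 0.05. The real counts were 9181 for FK228 versus control, 4357 for YF versus control, 10325 for the combination versus control, 9426 for the combination versus YF, 7063 for the combination versus FK228 and 8162 for FK228 versus YF. The highest other split gave 0 in each by edgeR.

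The first pattern weighed is that mitosis genes were lower with FK228 and not with YF, which the direct comparison of FK228 with YF also showed (41 of 41 lower). The tables argue against a trend on GC content or transcript length as the whole cause: after its removal the median of the list was -2.44, against -2.37 before, with library pairs from -2.52 to -2.26, all 41 members covered and a median absolute shift of 0.049 over all genes. A few genes taking more of the counts in FK228 libraries would lower all genes together, but under total-count scaling the median of all genes was -0.065 and that of the list -2.42. Reads from other cells and a difference in how the cultures were grown were not tested. The design names a biological difference, inhibition of class I HDACs by FK228, and a lower share of dividing cells is a candidate explanation that RNA levels alone do not test.

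The second pattern is the rise of H3c13, H3c11 and Fos with YF from near 0. If their reads came from 1 introduced transcript that also carries Hdac1, FK228 would raise them in YF cells as much as the Hdac1 excess over cells without YF, which rose by 1.18 ± 0.05. H3c13 rose by 1.56 ± 0.13, H3c11 by 1.69 ± 0.18 and Fos by 1.44 ± 0.08, and the smallest difference was 2.77 SE, which argues against a single transcript that also carries Hdac1. A transcript without Hdac1, separate transcripts, or parts of the YF vectors that match these genes, stay open because the construct sequences are not given in the sources used here. The sample descriptions give the libraries without YF a GFP code, and if it stands for a GFP vector, parts common to both vectors would give reads there too. H3c13 stood at 0.0389 CPM in control and 0.0827 with FK228, but the labels do not say what the code means. A general immediate early response, taken as a rise of 1 or more in the other immediate early genes, was also weighed. The median of the 22 tested was 0.20, with 7 higher and 2 lower. The list with Fos in it lay higher with YF by camera, as given above. A smaller response, or one of part of the list, thus stays open. Reads shared with other H3 genes cannot be told apart from a rise of H3c13 and H3c11 themselves. The other 5 tested H3 genes had a median of 1.07, but this reading was set after the value was seen, their SEs reach 0.97, and only H3c1 (3.68 ± 0.74) was called.

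The third pattern is that large positive log2 fold changes with FK228 were smaller with YF, which gave a slope of 0.615 over the raised genes. Rises in CPM were not compared. The pattern is not a smaller response of raised genes in general. Their median log2 fold change was 0.53 without YF and 0.55 with it. Of them, 778 had a negative interaction and 790 a positive one. At a mean CPM of 50 or more, 189 were negative and 398 positive. Folds inflated by near-zero control counts are a candidate cause: among raised genes with a mean CPM of 50 or more the slope was 1.071, between 1.038 and 1.093 without each replicate number. Prior induction by YF may also take part, since the slope was 0.552 among raised genes that YF also raises and 0.843 among those it does not call. At a mean CPM of 50 or more that order was the opposite, 1.171 against 0.962, and below 50 it was 0.528 against 0.835. Genes silent in control are the ones at issue in both readings, so these values do not separate them.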

How the results depend on the processing

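The comparison of FK228 with YF and the gene list tests without each library were chosen after seeing the data. The total numbers of genes called higher and lower in each comparison were compared with their main values. They stayed within 1.5 times under DESeq2 size factors (RLE scaling in edgeR), no count filter and a filter of 5 CPM in 3 libraries. The same held for DESeq2, limma-voom and the compared groups alone. Counts within a list could move more, as for the ribosomal protein genes lower with YF. No call of a named gene or gene list reversed under the alternatives run for it. With DESeq2 size factors, medians near 0 of lists whose median was not used for a direction changed sign: class I HDACs in FK228 versus control (-0.01 to 0.02), and in FK228 versus YF the TGF-beta (-0.02 to 0.03) and epithelial lists (-0.02 to 0.02). Without each of the 12 libraries, genes higher and lower ranged from 4176 to 4551 and 4327 to 4736 for FK228 versus control, 1939 to 2594 and 1422 to 2190 for YF versus control, 4946 to 5220 and 4959 to 5172 for the combination versus control, and 1138 to 1582 and 1674 to 2135 for the interaction. The genes shared by FK228 and YF in the same direction, 3207, ranged from 2577 to 3326. DESeq2 size factors moved the share of higher calls most for FK228 versus YF, from 45.5% to 50.6%.

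The slope of the FK228 effect with YF on that without, 0.776, became 0.949 with a filter of 5 CPM in 3 libraries, which removes the genes with few counts. It was 0.675 by least squares of the effect with YF on that without and 0.97 by the inverse, which differ by construction. It was 0.743 over genes called in FK228 versus control and 0.828 over genes called in the combination versus YF, and it ranged from 0.745 without control replicate 2 to 0.802 without YF replicate 1.

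With an estimated inter-gene correlation, lists passing camera went from 14 to 0 for FK228 versus control, from 12 to 1 for YF versus control, from 16 to 0 for the combination versus control, from 18 to 2 for the combination versus YF, from 15 to 3 for the combination versus FK228, from 9 to 2 for the interaction and from 21 to 3 for FK228 versus YF. A larger correlation widens the error of a list by construction. Of 105 calls of a list in a comparison, 94 were lost with it, 12 without some library and 1 with DESeq2 size factors. Of 1090 pairs of a named gene and a comparison, 69 lost the call under some alternative, and leaving out 1 library ended calls 293 times over the 12 libraries. Of the calls of named genes, 6 were lost with DESeq2, 9 with limma-voom and 0 with DESeq2 size factors.

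Replicate numbers do not pair the libraries: of 18 same-numbered pairs 0 had a correlation of deviations over 0.1 (from -0.215 to 0.089), and 1 of 12 libraries correlated best with its own number. With the replicate number as a block, 4356 genes were higher and 4659 lower for FK228 versus control, 2260 and 1796 for YF versus control, 5116 and 5096 for the combination versus control, and 1324 and 1820 for the interaction. The block ended 17 calls of named genes and 0 of lists.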

Other observations

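No test was added for the values in this part. Marker lists show which kinds of transcript the control AML12 libraries held, as levels only, in CPM without TMM factors. The median control CPM was 0.0193 for endothelial markers, 0.0451 for hepatic stellate cell markers and 0.341 for macrophage and leukocyte markers, whose highest genes were Esam at 4.837, Ecm1 at 26.02 and Cd14 at 153.7 CPM. Hepatocyte identity genes had a median of 0.887 CPM, with Apob at 427.9 and 12 members at 10 CPM or more. Cholangiocyte and progenitor markers had a median of 64.5 CPM, with Spp1, which encodes osteopontin, at 4167.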
